A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

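Gene expression was measured on 8 Affymetrix Yeast Genome 2.0 arrays, 1 culture per array, in an industrial Saccharomyces cerevisiae strain and in a strain adapted from it that tolerates inhibitors. The 4 groups were the parental strain without inhibitors, the parental strain with a mixture of inhibitors, the tolerant strain without inhibitors and the tolerant strain with the mixture, with 2 biological replicates each as the labels call them. Per the labels' protocols, 5 L fermentors that were not aerated held 3 L of rich medium with 20 g peptone, 10 g yeast extract and 100 g glucose per litre, and cells were harvested in mid-exponential phase. RNA was extracted with hot phenol and labelled by the array maker's procedure, per the labels' protocols. The composition and dose of the inhibitor mixture and the way the tolerant strain was adapted are not given in the sources used here.

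The deposited values are intensities on a linear scale, 1 per probe set. Per the submitters' processing notes, they came from GCOS, the Affymetrix operating software, whose version is not given in the sources used here. How the probes were summarised and to what target each array was scaled is likewise not given in the sources used here. The medians of the 10928 deposited intensities lay between 73.5 and 86.1 over the 8 arrays, and the highest intensity on any array was 18931. Intensities of different probe sets were not set against each other, except in the ratios of 3' to 5' control probe sets of the same transcript. The number of arrays limits the precision of every value.

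The platform annotation paired 5498 probe sets with 1 S. cerevisiae gene each, which made 5449 different genes, 47 of them with more than 1 probe set. Another 1746 probe sets belong to 1 gene of another species (the array also carries Schizosaccharomyces pombe), 1 has several genes, 3517 are unnamed here and 166 are controls. Symbols were updated through the gene ID in 12 cases. Control and other-species probe sets were left out of the tests, and unnamed probe sets were tested but are not named. A gene with several probe sets was represented by the one with the highest mean. Probe sets of near-identical paralogues, such as pairs of ribosomal protein genes or HXT6 and HXT7, and of multicopy Ty elements can share signal, so values of single members are uncertain to that extent.

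The other-species probe sets gave the background: a probe set was tested where its mean log2 intensity over the 8 arrays lay above the 95th percentile of theirs, which was 5.41 (an intensity of 41.6). This left 5674 features, of which 5266 were named genes and 407 were unnamed probe sets, and it removed 183 named genes. Values were taken as log2(intensity + 1), which slightly understates fold changes of dim genes. No further normalization between arrays was applied, because the medians of the S. cerevisiae probe sets on the log2 scale lay between 9.41 and 9.60. The same percentile on each array gave that array's own background, an intensity between 38.0 and 60.4. Where a gene lay at or below it on both arrays of a group, the fold is given as "at least N-fold": the brighter group's mean over the dimmer group's mean of, per array, the higher of that background and the gene's own value. With such genes at their bounds, the list median that moved most did so by 0.47 on the log2 scale in the parental response (sporulation genes), by 0.09 in the tolerant response (sporulation genes), by 0.29 between the strains without inhibitors (sporulation genes) and by 0.13 between them with inhibitors (mating-type genes).

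Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend). All 4 groups were fitted in 1 cell-means model with 4 residual degrees of freedom, to which the moderation added 7.80 prior degrees of freedom. The tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. A p-value sets a difference between groups against the spread between these cultures, pooled over the 4 groups. It does not cover the spread between other parental or tolerant strains. The pooling gives every group the same spread, although the replicates of some groups lay closer than those of others. There were 5 comparisons: the inhibitor response of each strain, the tolerant against the parental strain without and with inhibitors, and the difference between the strains in their response (the interaction). Gene lists were tested with camera at its preset correlation of 0.01 between genes, and again with a correlation estimated per list, for 43 lists with at least 5 measured members. The lists hold pathways of fermentation, growth and stress and markers of other yeast cell types and states. Of their 1173 entries, 12 had no matching gene and 28 were not on the array under 1 gene. No list called at the preset correlation was called with an estimated correlation in any of the 5 comparisons. The estimated correlations rest on only 4 residual degrees of freedom, and the power of that second test was not checked. A list it did not call is therefore not shown to be unchanged.

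The groups, the tests, the lists, the background filter, the alternatives and the rule for naming genes were set before the data were examined. The rule names, for each comparison, the 8 largest rises and the 8 largest falls among genes that passed with the 2 arrays of one group on one side of both arrays of the other (a condition not used for the interaction), up to 4 members with the smallest p of each list described, and 15 fixed genes: ADH6, ADH7, ARI1, GRE2, ALD6, ZWF1, PDR5, PDR12, TPO1, YRO2, HSP12, HSP26, GPD1, HXT1 and FLO11. Genes named outside this rule are said to be so where they appear. Alternatives covered other pseudocounts (16 and 64), no filter or a stricter one (mean log2 at least 1 above background), quantile normalization, centring each array on its median, other variance models, a fit of the 4 arrays of a comparison alone, a replicate block, all probe sets, stricter thresholds (an adjusted p under 0.01, or a 2-fold change), and leaving out each array in turn.

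The tests were checked on simulated data drawn from the spread of these arrays over 5674 features. With 100 genes changed by 1 on the log2 scale, 98% were recovered for the parental response, 99% for the tolerant response and for both strain comparisons, and 95% for the interaction. At a change of 0.5, recovery was 86%, 89%, 84%, 89% and 62% in the order of the 5 comparisons above, with between 3 and 9 false calls. Camera called 0 lists in 20 simulated sets for the parental response with no change, and it called a list of 38 genes that was shifted by 0.3. The simulated genes varied independently of each other, so this check cannot show how often camera calls lists whose genes vary together. The simulated noise was normal with its spread taken from the fit, so the false calls of the gene test hold only under those conditions. On the real arrays the gene test called 217 of 1746 other-species probe sets in the parental response and 12 in the tolerant response.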

Results

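The data set holds 8 arrays of yeast RNA from mid-exponential fermentations, 2 biological replicates for each of 4 groups: an industrial parental strain (labelled angel yeast) and a tolerant strain adapted to inhibitors, each grown without and with a mixture of inhibitors. The series asks how the transcriptomes of both strains respond to the mixture. Log2 differences are given ± their standard error from the fit, and intensities as mean ± SD (n = 2 arrays). A change given without a unit is on the log2 scale.

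Replicates lay close together. The SD of the log2 difference between the 2 arrays of a group was 0.17 in the parental strain without inhibitors, 0.20 in the parental strain with them, 0.16 in the tolerant strain without and 0.12 in the tolerant strain with inhibitors. The first principal component held 66.1% of the variance and set the 2 parental arrays with inhibitors (scores 62.8 and 60.1) apart from the other 6 (between -33.2 and -3.34). The second held 22.1% and set apart the tolerant arrays with inhibitors (scores 35.5 and 36.9). The ratio of 3' to 5' control probe sets of ACT1 was between 1.29 and 1.36 on all arrays. For SPT15 it was between 3.78 and 4.07 without and between 4.94 and 5.30 with inhibitors in both strains. For TDH1 it was between 1.17 and 1.27 without and between 1.07 and 1.13 with inhibitors, and for RIP1 between 0.873 and 1.03 on all arrays. For WBP1 it was between 1.81 and 2.00 in the parental and between 2.40 and 2.51 in the tolerant strain. For EAF5, a dim transcript, it was between 2.07 and 2.65 without and between 2.54 and 3.13 with inhibitors. For SRB4 it was between 10.1 and 14.4 in the parental and between 17.6 and 21.1 in the tolerant strain. Its 5' intensities lay between 45.4 and 89.3, close to background, so the size of that ratio is uncertain.

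In the parental strain, the inhibitors were accompanied by lower transcripts of the translation machinery and higher transcripts of reserve carbohydrate, alternative carbon and phosphate metabolism. Each of the 124 measured cytosolic ribosomal protein genes fell, with a median log2 change of -2.14, and so did each of the 90 ribosome biogenesis genes, with a median of -3.19. RPL9A, which encodes a protein of the large ribosomal subunit, went from an intensity of 9185 ± 527 to 515 ± 10.6, a log2 change of -4.15 ± 0.06 (adjusted p = 1.5e-13). BIO5 (YNR056C), a biotin pathway gene, rose 84.8-fold (log2 6.41 ± 0.12, adjusted p = 3.6e-13, 1 of its 2 arrays without inhibitors above background). Of 5674 features, 2274 were higher and 2314 lower with inhibitors, 904 and 964 of them by at least 2-fold and 95 and 137 by at least 8-fold.

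Among the other genes with the largest rises, OYE3, an NADPH-dependent oxidoreductase of the old yellow enzyme family, rose at least 39.4-fold, reaching 2289 ± 0.955. POX1, the acyl-CoA oxidase of peroxisomal beta-oxidation, rose at least 12.5-fold, and the little-characterised YJR154W and YOL131W rose at least 17.5-fold and at least 12.5-fold. The places of POX1, YJR154W and YOL131W among the largest rises rest on values at background, and some genes named below rose by more than these bounds. PHO5, the repressible acid phosphatase, rose 34.8-fold to 9011 ± 428. GPH1, glycogen phosphorylase, rose 33.6-fold (log2 5.07 ± 0.08) and BIO3, another gene of biotin synthesis, 32.0-fold. AAH1, adenine deaminase, fell 44.9-fold from 3283 ± 100.4 to 72.3 ± 7.38. URA7, a CTP synthase, fell 30.0-fold. The other large falls were in genes of ribosome production: RPA43, a subunit of RNA polymerase I, fell at least 21.7-fold, SYO1, an import adaptor for ribosomal proteins, at least 22.2-fold, and MAK21 23.3-fold. ROK1, UTP13 and RRP3 fell 23.0-fold, 22.6-fold and 21.9-fold, with 1 of the 2 arrays with inhibitors above background for each.

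The fall of the ribosomal protein list (camera adjusted p = 9.8e-35) and of the ribosome biogenesis list (camera adjusted p = 1.6e-25) had an adjusted p = 0.3 with an estimated correlation in both cases. RPS8B, RPS24B and RPS11A fell, with log2 changes of -3.13, -3.09 and -3.52, and so did the genes of the ribosome assembly factors ERB1 (-4.22), RRP5 (-3.83), HAS1 (-3.81) and DBP2 (-3.46). Of the ergosterol genes, 24 of 26 fell and 1 rose (camera adjusted p = 4.1e-06, and adjusted p = 0.3 with an estimated correlation). They included CYB5 (-2.63 ± 0.07), HMG1 (-2.32 ± 0.06), which encodes HMG-CoA reductase, ERG8 (-1.40 ± 0.06) and ERG13 (-1.15 ± 0.05). Of the genes of DNA replication and the G1/S transition, 27 of 30 fell and 1 rose (camera adjusted p = 5.7e-05, and adjusted p = 0.3 with an estimated correlation), among them POL30, the replication clamp (-1.89), POL12 and POL1 of DNA polymerase alpha (-2.13 and -1.66) and the cyclin gene CLB6 (-1.94). Of the aromatic amino acid and histidine genes 14 of 19 fell and 2 rose (camera adjusted p = 0.0086, and adjusted p = 0.31 with an estimated correlation).

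Genes of reserve carbohydrates and of stationary cells rose together. All 19 trehalose and glycogen genes rose (median 1.64, camera adjusted p = 4.8e-07, and adjusted p = 0.3 with an estimated correlation), including GDB1, the glycogen debranching enzyme (3.63 ± 0.07), GSY2, glycogen synthase (3.37 ± 0.08), and GAC1, a phosphatase subunit that acts on glycogen synthase (3.05 ± 0.08). All 26 genes of the stationary phase list rose (median 1.98, camera adjusted p = 7.2e-10, and adjusted p = 0.12 with an estimated correlation), among them FMP16 (4.63 ± 0.09), DCS2 (3.56 ± 0.07), SNO1, a vitamin B6 gene (4.24 ± 0.10), and GRE1, at least 25.9-fold. Of the sporulation genes 14 of 23 rose and 3 fell (median 0.84), and the list was not called (camera adjusted p = 0.091). With members at background set at their bounds, this median moved by 0.47. Of the phosphate starvation genes 17 of 19 rose and 2 fell (camera adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation). PHO89, a phosphate transporter, rose by 3.80 and PHO11 by 2.82, and PHO3, the constitutive acid phosphatase, fell by 2.21.

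Genes of respiration and of carbon sources other than glucose were higher. In the gluconeogenesis and glyoxylate list 11 of 13 rose and 1 fell (median 2.11, camera adjusted p = 4.3e-04, and adjusted p = 0.3 with an estimated correlation). JEN1, the lactate transporter, rose by 2.95, ADY2, an acetate transporter, by 3.89 (1 of 2 arrays without inhibitors above background), MLS1, malate synthase, by 3.45 and CRC1, the mitochondrial carnitine carrier, by 2.87. Of the TCA cycle genes 19 of 20 rose and 0 fell (camera adjusted p = 4.1e-06, and adjusted p = 0.3 with an estimated correlation), with LSC2 at 2.75 ± 0.08, SDH4 at 1.89 ± 0.07, SDH1 at 1.86 ± 0.08 and SDH2 at 1.75 ± 0.07. Of the respiratory chain and ATP synthase genes 30 of 35 rose and 1 fell (camera adjusted p = 1.0e-05, and adjusted p = 0.33 with an estimated correlation): NDE2, an external NADH dehydrogenase, rose at least 10.0-fold, COX5B rose by 1.71 and NDI1 by 1.51, and CYC1, cytochrome c isoform 1, fell by 1.44. Mitochondrial ribosomal protein genes rose in 44 of 53 cases and fell in 1 (camera adjusted p = 4.1e-06, and adjusted p = 0.3 with an estimated correlation). Of the genes under nitrogen catabolite repression 23 of 27 rose and 3 fell (camera adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation), with the ammonium transporter gene MEP2 at 2.16 ± 0.09, UGA2 at 2.06 ± 0.07, PUT1 at 2.01 ± 0.09 and UGA1 at 1.66 ± 0.06.

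Genes of oxidative stress, aldehyde conversion, drug export and sulfur assimilation also rose in the parental strain. Of the oxidative stress genes 27 of 33 rose and 4 fell (camera adjusted p = 2.9e-05, and adjusted p = 0.3 with an estimated correlation), including ECM4 and GTT1, both glutathione transferases (3.76 ± 0.08 and 3.13 ± 0.07), PRX1, a peroxiredoxin (2.90 ± 0.07), and GPX1 (2.12 ± 0.08). Of the aldehyde reductases and dehydrogenases 18 of 23 rose and 1 fell (camera adjusted p = 1.4e-04, and adjusted p = 0.3 with an estimated correlation), with ALD3 at 3.52 ± 0.08, BDH2 at 3.40 ± 0.09 and GCY1 at 2.92 ± 0.08. Of the multidrug transport genes 15 of 25 rose and 5 fell (camera adjusted p = 0.016, and adjusted p = 0.3 with an estimated correlation), with PDR15 at 3.56 ± 0.09, AQR1 at 3.07 ± 0.09, FLR1 at 2.07 ± 0.07 and RSB1 at 1.85 ± 0.08. Of the sulfur amino acid genes 22 of 31 rose and 4 fell (camera adjusted p = 0.0013, and adjusted p = 0.3 with an estimated correlation), led by SUL2, a sulfate permease (4.65 ± 0.13, 1 of 2 arrays without inhibitors above background), MET13 (3.56 ± 0.10), MET10 (3.09 ± 0.08) and MET17 (2.44 ± 0.06). Heat shock genes went both ways, 10 of 29 rising and 8 falling (camera adjusted p = 0.43). The list median was 0.08 as deposited and 0.42 after quantile normalization, so its size depends on the scaling of the arrays. HSP31 rose by 2.31, HSP12, a membrane-associated stress protein, by 2.28, APJ1 by 1.21 and HSP26 by 1.01.

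Of the fixed genes, ZWF1, glucose-6-phosphate dehydrogenase, rose by 2.00, FLO11 by 1.57, YRO2 by 0.85, GRE2 by 0.69 and ALD6 by 0.27 in the parental strain. ADH6, an NADPH-dependent alcohol dehydrogenase that reduces aldehydes, fell by 0.40, PDR5, a multidrug exporter, fell by 0.20 and HXT1, a low-affinity glucose transporter, fell by 0.76. The changes of ADH7 (0.13 ± 0.15), ARI1 (0.00 ± 0.07), PDR12 (0.06 ± 0.08) and TPO1 (0.06 ± 0.06) did not pass the test, nor did that of GPD1 (-0.07 ± 0.05), which passed as a rise of 0.31 after quantile normalization. In total camera called 15 lists higher and 5 lower, and 0 with an estimated correlation (6 at an unadjusted p under 0.05). The ratio of 3' to 5' probe sets of SPT15 rose with the inhibitors in this strain, from 3.78 and 4.07 to 4.94 and 5.19, and that of TDH1 went down from 1.21 and 1.17 to 1.07 and 1.08. Adjusted over the list alone, the counts of members of the lists described for this comparison were the same.

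**Figure D1:**
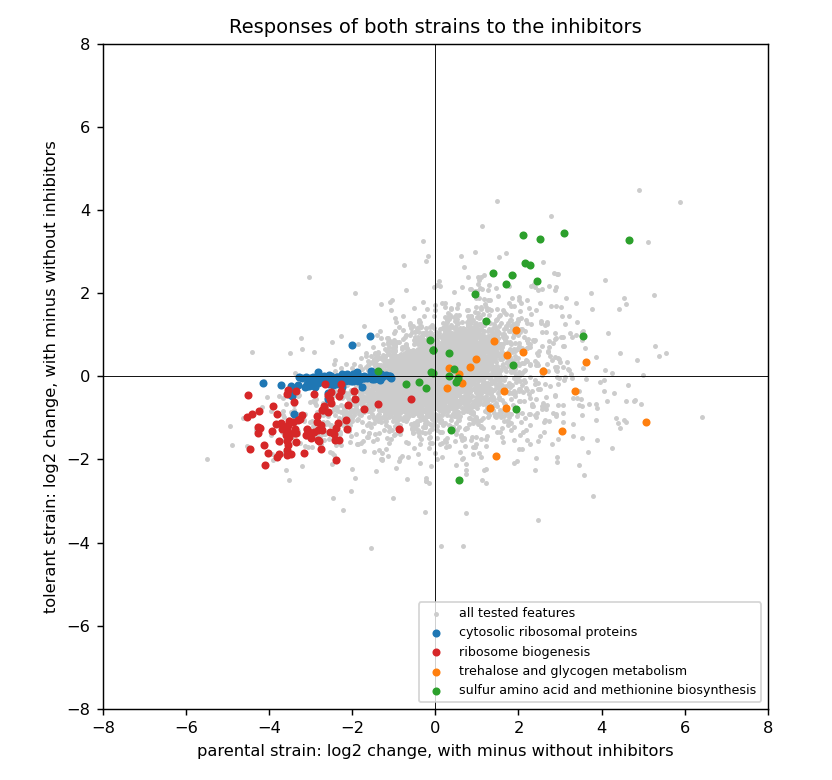
Log2 change with inhibitors in the parental strain (horizontal) against the tolerant strain (vertical) for 5674 tested features, 1 point each, with 4 gene lists in colour. Ribosomal protein genes lie along the horizontal axis (medians -2.14 and -0.05), and ribosome biogenesis genes lie below 0 in both strains (medians -3.19 and -1.23).

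In the tolerant strain, genes of sulfate assimilation, aldehyde conversion, the pentose phosphate pathway and respiration rose with inhibitors, and purine, ribosome biogenesis and proteasome genes fell. MET10 (YFR030W), a subunit of sulfite reductase, rose 11.0-fold from 341 ± 4.32 to 3747 ± 136 (log2 3.45 ± 0.08, adjusted p = 1.2e-11). GRE2 (YOL151W), an NADPH-dependent methylglyoxal reductase, rose 6.24-fold from 1791 ± 10.8 to 11182 ± 285 (log2 2.64 ± 0.05, adjusted p = 6.4e-12). ADE17, a bifunctional enzyme of purine synthesis, fell 9.68-fold from 4913 ± 49.6 to 507 ± 6.31 (log2 -3.28 ± 0.06, adjusted p = 4.2e-12). Of 5674 features, 1886 were higher and 1971 lower, 357 and 436 of them by at least 2-fold and 11 and 7 by at least 8-fold.

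The largest rises were those of GPG1 (22.4-fold), YDR248C, a putative gluconokinase (18.6-fold), OYE3 (18.5-fold) and HBN1, a protein related to bacterial nitroreductases (14.5-fold). They were followed by 4 genes of sulfate uptake and reduction: MET10, MET3, the ATP sulfurylase (10.6-fold), MET5 of sulfite reductase (9.83-fold) and SUL2 (9.77-fold). YFL051C, a gene related to flocculins, fell at least 16.3-fold. CAR2, ornithine transaminase of arginine breakdown, fell 17.0-fold and TIR3, a cell wall mannoprotein, 16.9-fold. PHO84, the high-affinity phosphate transporter, fell 11.0-fold, PRM7 9.32-fold, YJL218W 7.65-fold and FTR1, the high-affinity iron permease, 7.54-fold.

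Of the sulfur amino acid genes 18 of 31 rose and 5 fell (median 0.64, camera adjusted p = 2.7e-04, and adjusted p = 0.47 with an estimated correlation), with MET17 at 2.29 ± 0.06. Of the aldehyde reductases and dehydrogenases 17 of 23 rose and 5 fell (camera adjusted p = 0.0013, and adjusted p = 0.47 with an estimated correlation), with GCY1 at 2.47 ± 0.08. ALD6, the main cytosolic acetaldehyde dehydrogenase, fell by 1.47. In the pentose phosphate pathway 8 of 11 rose and 1 fell (camera adjusted p = 0.0033, and adjusted p = 0.42 with an estimated correlation): SOL3 rose by 1.65, GND2 by 1.55 and GND1 by 0.93, and RKI1, ribose-5-phosphate isomerase, fell by 1.61. Lysine genes rose in 8 of 9 cases (camera adjusted p = 8.1e-04, and adjusted p = 0.47 with an estimated correlation), with LYS14 at 1.35 ± 0.08, LYS20 at 1.10 ± 0.06, LYS9 at 1.10 ± 0.06 and LYS1 at 0.84 ± 0.06. Of the vitamin B6 and NAD genes 10 of 17 rose (11 adjusted over the list alone) and 3 fell (camera adjusted p = 0.047, and adjusted p = 0.47 with an estimated correlation); the leading members BNA1 (2.21), BNA2 (2.11), BNA3 (1.48) and BNA6 (1.39) are NAD synthesis genes.

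Of the respiratory chain and ATP synthase genes 33 of 35 rose and 2 fell (median 0.88, camera adjusted p = 3.0e-11, and adjusted p = 0.47 with an estimated correlation), including ATP15 (1.35 ± 0.06), QCR10 (1.28 ± 0.07), QCR2 (1.24 ± 0.06) and COR1 (1.17 ± 0.06). TCA cycle genes rose in 17 of 20 cases and fell in 1 (camera adjusted p = 3.3e-06, and adjusted p = 0.49 with an estimated correlation), with SDH2 at 1.29 ± 0.07, KGD2 at 1.05 ± 0.07, IDP1 at 1.03 ± 0.06 and SDH3 at 0.89 ± 0.05. Of the mitochondrial ribosomal protein genes 43 of 53 rose (44 adjusted over the list alone) and 0 fell (camera adjusted p = 1.8e-08, and adjusted p = 0.42 with an estimated correlation), with MRPL44 at 1.75 ± 0.08, RSM27 at 1.26 ± 0.08, MRPL15 at 1.15 ± 0.09 and MRPL51 at 0.95 ± 0.08. Oxidative stress genes rose in 18 of 33 cases (19 adjusted over the list alone) and fell in 6 (camera adjusted p = 0.0065, and adjusted p = 0.64 with an estimated correlation).

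Purine genes fell in 16 of 18 cases and rose in 2 (median -1.32, camera adjusted p = 2.7e-06, and adjusted p = 0.42 with an estimated correlation), with GCV2 at -2.07 ± 0.08, ADE1 at -1.72 ± 0.06 and SHM2 at -1.64 ± 0.06. Of the 90 ribosome biogenesis genes 87 fell (median -1.23, camera adjusted p = 5.1e-20, and adjusted p = 0.47 with an estimated correlation), among them HAS1, DBP2, NOP13 and YTM1, with log2 changes of -1.93, -1.86, -1.84 and -1.65. The median of the cytosolic ribosomal protein genes was -0.05, with 3 of 124 rising and 27 falling (2 and 22 adjusted over the list alone), and the list was not called (camera adjusted p = 0.12). RPS14B fell by 0.91 and RPS11A fell by 0.41, and RPL9B and RPS28B rose by 0.98 and 0.75. Proteasome genes fell in 26 of 38 cases and rose in 1 (camera adjusted p = 7.5e-04, and adjusted p = 0.64 with an estimated correlation), among them RPN7 (-0.81 ± 0.07), RPT5 (-0.70 ± 0.06), RPN11 (-0.65 ± 0.07) and RPT3 (-0.61 ± 0.06). Of the heat shock genes 20 of 29 fell and 4 rose (camera adjusted p = 0.0065, and adjusted p = 0.68 with an estimated correlation): the chaperone genes YDJ1 (-0.93) and SIS1 (-0.70) and the membrane protein gene HSP30 (-0.75) fell, and HSP31 rose by 2.17. The ergosterol list was called lower with 14 of 26 members falling and 2 rising (camera adjusted p = 0.047, and adjusted p = 0.69 with an estimated correlation).

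The multidrug list was not called (15 of 25 rose, 7 fell, camera adjusted p = 0.051). PDR5 rose 3.06-fold from 3029 ± 36.0 to 9279 ± 114 and YOR1, another exporter, rose by 1.68. QDR2 (-1.92) and HXT9 (-1.74) fell. Of the fixed genes, ADH6 rose 2.29-fold to 11116 ± 105, ZWF1 rose by 1.33, YRO2 by 0.90, ARI1, which reduces aldehydes, by 0.85, FLO11 by 0.66, HSP26 by 0.48, TPO1 by 0.31, PDR12 by 0.21, HXT1 by 0.20 and GPD1 by 0.15. HSP12 fell by 0.51, and the change of ADH7 (-0.31 ± 0.15) did not pass. In total camera called 9 lists higher and 5 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). The 3' to 5' ratio of SPT15 went from 3.86 and 3.95 to 4.94 and 5.30 with inhibitors, and that of TDH1 from 1.25 and 1.27 to 1.09 and 1.13. Adjusted over the list alone, the other lists described for this comparison had the same counts of members.

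**Figure D2:**
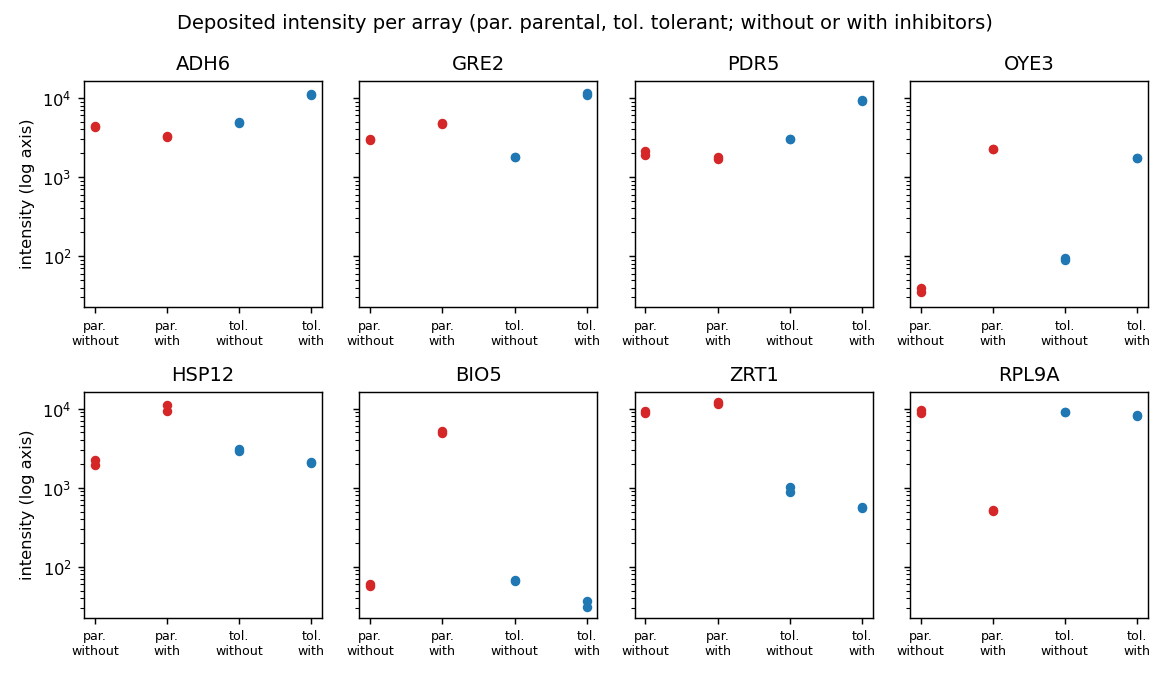
Deposited intensity (log axis) of 8 genes on each of the 8 arrays, with red points for the parental and blue points for the tolerant strain, without and with inhibitors. ADH6, GRE2 and PDR5 have their highest values in the tolerant strain with inhibitors, HSP12 and BIO5 in the parental strain with inhibitors, and RPL9A its lowest there (mean 515).

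Set side by side, the responses of the strains overlapped in part. Across genes, which are not independent replicates, the 2 log2 responses had a Pearson r of 0.361 and a Spearman rho of 0.364, with no array in common. Both strains had 1152 features higher (756 from independent lists of these sizes) and 1117 lower (804). The features that changed in opposite directions were 550 higher in the parental and lower in the tolerant strain and 400 the other way. At least 2-fold in both strains were 178 higher (56.9 from independent lists) and 206 lower (74.1). Of the 904 features at least 2-fold higher in the parental strain 236 were lower in the tolerant strain, and of the 964 lower 81 were higher. Of the 357 at least 2-fold higher in the tolerant strain 42 were lower in the parental strain, and of the 436 lower 127 were higher.

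The test of the difference between the responses asks which genes reacted differently. The ribosomal protein list had a median difference of 2.09 on the log2 scale (tolerant minus parental response), with 124 of 124 members higher (camera adjusted p = 5.9e-39, and adjusted p = 0.37 with an estimated correlation). The ribosome biogenesis list had 1.95 (87 of 90 higher, camera adjusted p = 1.2e-19, and adjusted p = 0.4 with an estimated correlation). On the opposite side, the gluconeogenesis list had a median of -2.89 (camera adjusted p = 4.2e-05, and adjusted p = 0.22 with an estimated correlation), the stationary phase list -2.31 (camera adjusted p = 4.1e-08, and adjusted p = 0.087 with an estimated correlation) and the phosphate starvation list -1.90 (camera adjusted p = 7.9e-06, and adjusted p = 0.087 with an estimated correlation). The response was higher in the tolerant strain for 2229 features and lower for 1915.

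Genes whose response was higher in the tolerant strain were led by SFG1, a putative transcription factor gene of pseudohyphal growth (5.42 ± 0.13), the ribosome assembly genes CGR1 (5.00 ± 0.37), UTP13 (4.06 ± 0.13) and RRP36 (3.88 ± 0.32), the ribosomal protein genes RPL22B (4.16 ± 0.11), RPL41A (4.04 ± 0.11) and RPL9A (4.01 ± 0.08), and the S phase cyclin gene CLB6 (3.94 ± 0.15). With inhibitors, RRP36 was above background on 0 of the 2 parental arrays and SFG1, CGR1 and UTP13 on 1 of 2. The sizes of these 4 differences rest in part on values at background. RPL22A, RPS24B and RPS8B had differences of 3.17, 2.91 and 2.87, and UTP18, ERB1 and RRP5 of 3.15, 2.97 and 2.68. Lysine genes had a higher response in 8 of 9 cases (median 1.82, camera adjusted p = 0.0024, and adjusted p = 0.55 with an estimated correlation), with LYS4 at 2.72 ± 0.09, LYS9 at 2.42 ± 0.08, LYS20 at 1.88 ± 0.08 and LYS12 at 1.82 ± 0.07. Among the fixed genes, GRE2 (1.95 ± 0.08), PDR5 (1.82 ± 0.09), ADH6 (1.60 ± 0.07), HXT1 (0.97 ± 0.08) and ARI1 (0.85 ± 0.10) had a higher response in the tolerant strain. TPO1 (0.25 ± 0.09) and GPD1 (0.21 ± 0.07) did so too, and both changed sign after quantile normalization (-0.11 and -0.18).

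Genes whose response was lower in the tolerant strain were led by BIO5 (-7.38 ± 0.17), the phosphate transporter genes PHO89 (-6.67 ± 0.15) and PHO84 (-5.94 ± 0.13), GPH1 (-6.17 ± 0.11), FMP45 (-5.96 ± 0.14), SNO1 (-5.96 ± 0.14), YOR186W (-5.69 ± 0.15) and DSF1 (-5.68 ± 0.17). BIO5 was above background on 0 of the 2 tolerant arrays with inhibitors and on 1 of 2 parental arrays without, and YOR186W and DSF1 on 0 of 2 parental arrays without inhibitors. The sizes of these 3 differences are no bounds. In the gluconeogenesis list ADY2 had -4.65 ± 0.15 (1 of 2 parental arrays without inhibitors above background), MLS1 -3.79 ± 0.17, MDH2 -3.44 ± 0.12 and JEN1 -3.13 ± 0.11. In the trehalose and glycogen list (median -1.53, camera adjusted p = 6.4e-08, and adjusted p = 0.37 with an estimated correlation) GAC1 had -4.36 ± 0.12, GSY2 -3.73 ± 0.11 and GSY1 -3.37 ± 0.10. SNZ1 and MPC3 of the stationary phase list had -4.74 ± 0.11 and -3.86 ± 0.10, and PHM7 and VTC4 of the phosphate list -3.44 ± 0.11 and -2.25 ± 0.09. Of the fixed genes, HSP12 (-2.79 ± 0.12), ALD6 (-1.74 ± 0.09), FLO11 (-0.91 ± 0.18), ZWF1 (-0.67 ± 0.11) and HSP26 (-0.52 ± 0.10) had a lower response, and ADH7 (-0.44 ± 0.21), PDR12 (0.15 ± 0.11) and YRO2 (0.04 ± 0.07) did not pass, though YRO2 passed with -0.29 after quantile normalization. In total 4 lists had a higher and 12 a lower response in the tolerant strain by camera, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Adjusted over the list alone, the member counts given here were the same.

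Without inhibitors, the median size of the log2 difference between the strains was 0.26, against 0.65 for the parental and 0.39 for the tolerant response. Genes of reserve carbohydrates, hexose transport and gluconeogenesis were higher in the tolerant strain, and genes tied to zinc uptake, mating pheromone and Ty elements were among the largest falls. MTH1 (YDR277C), a repressor of hexose transporter genes, was 13.9-fold higher, at 1698 ± 112 against 121 ± 6.02 (log2 3.80 ± 0.08, adjusted p = 5.6e-11). ZRT1 (YGL255W), the high-affinity zinc transporter, was 9.50-fold lower, at 961 ± 101 against 9117 ± 347 (log2 -3.25 ± 0.08, adjusted p = 5.6e-11). Of 5674 features, 2071 were higher and 983 lower in the tolerant strain, 308 and 83 of them by at least 2-fold. Quantile normalization gave 1450 higher and 1496 lower and centring each array 1492 and 1554. The median over all features was 0.09 as deposited and -0.02 after quantile normalization, so a difference of this size has no settled direction.

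The other large rises were those of GPH1 (9.95-fold), HXK1, a hexokinase isoenzyme (8.44-fold), MAL32, a maltase (8.78-fold), GAC1 (8.16-fold) and CIN5, a stress transcription factor (7.94-fold). REG2, a phosphatase regulator, was at least 9.01-fold higher and XBP1, a transcriptional repressor, at least 7.71-fold. The largest falls were those of VEL1 (19.5-fold) and ZPS1 (15.8-fold), which like ZRT1 and ADH4, an alcohol dehydrogenase isoenzyme (5.06-fold), are known to respond to zinc shortage. By their systematic names, ZRT1 (YGL255W), ADH4 (YGL256W) and VEL1 (YGL258W) are near neighbours on the same chromosome arm. They may therefore not count as separate cases, and a local change there was not tested. MF(ALPHA)1, the alpha-factor pheromone gene, was 11.2-fold lower. The Ty element reading frames YAR009C, YDR261W-B and YBL100W-B, whose probe sets can detect many copies, were 13.4-fold, 5.92-fold and 5.40-fold lower, with 1 of 2 tolerant arrays above background for YAR009C.

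Of the gluconeogenesis genes 11 of 13 were higher and 1 lower in the tolerant strain (median 1.31, camera adjusted p = 1.8e-04, and adjusted p = 0.46 with an estimated correlation), with ICL1, isocitrate lyase, at 2.92 ± 0.10, CRC1 at 2.84 ± 0.11, ADY2 at 2.41 ± 0.10 (1 of 2 parental arrays above background) and JEN1 at 2.07 ± 0.08. Trehalose and glycogen genes were higher in 12 of 19 cases and lower in 1 (camera adjusted p = 0.0025, and adjusted p = 0.49 with an estimated correlation), with GSY1 at 1.26 ± 0.07 and GLC3 at 1.24 ± 0.06. Of the stationary phase genes 17 of 26 were higher (18 adjusted over the list alone) and 5 lower (camera adjusted p = 0.0027, and adjusted p = 0.46 with an estimated correlation), with FMP16 at 2.58 ± 0.09, MPC3 at 2.57 ± 0.07 and PIR3 at 2.18 ± 0.09. Sporulation genes were higher in 13 of 23 cases (14 adjusted over the list alone) and lower in 2 (median 0.58), and the list was not called (camera adjusted p = 0.15). With members at background set at their bounds, this median moved by 0.29. Hexose transporter genes were higher in 10 of 13 cases and lower in 0 (camera adjusted p = 0.0035, and adjusted p = 0.49 with an estimated correlation): HXT9 at 1.67 ± 0.10, HXT4 at 1.36 ± 0.06, HXT7 at 1.26 ± 0.06 and HXT2 at 0.82 ± 0.07. All 38 proteasome genes were higher, by a median of 0.44 (0.29 after quantile normalization, camera adjusted p = 2.1e-06, and adjusted p = 0.49 with an estimated correlation), with RPN10 at 0.95 ± 0.06, PUP3 at 0.71 ± 0.07, RPN12 at 0.64 ± 0.06 and SCL1 at 0.56 ± 0.06.

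Respiratory chain genes were higher in 27 of 35 cases (28 adjusted over the list alone) and lower in 0 (median 0.42, or 0.25 after quantile normalization, camera adjusted p = 6.3e-05, and adjusted p = 0.49 with an estimated correlation). TCA cycle genes were higher in 13 of 20 and lower in 1 (camera adjusted p = 0.004, and adjusted p = 0.59 with an estimated correlation). Oxidative stress genes were higher in 19 of 33 cases (20 adjusted over the list alone) and lower in 2 (camera adjusted p = 0.004, and adjusted p = 0.55 with an estimated correlation). In the haploid and mating-type list 5 of 28 were higher and 10 lower (camera adjusted p = 0.024, and adjusted p = 0.49 with an estimated correlation), with MF(ALPHA)1 at -3.49 ± 0.19, STE2, the alpha-factor receptor gene of a cells, at -2.17 ± 0.20 (1 of 2 tolerant arrays above background), MF(ALPHA)2 at -1.52 ± 0.17 and STE4, a subunit of the pheromone G protein, at 0.86 ± 0.11. The nitrogen catabolite repression list was not called (camera adjusted p = 0.23), though PUT1 (2.65 ± 0.09), PUT4 (1.83 ± 0.12, 1 of 2 parental arrays above background) and CAR1 (0.86 ± 0.06) were higher and DAL4 was at least 4.96-fold higher. The cytosolic ribosomal proteins were called lower with a median of -0.01 and 5 of 124 members higher and 4 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.033, and adjusted p = 0.89 with an estimated correlation). This call sets members that hardly moved against an array-wide median of 0.09. The ribosome biogenesis list was not called (camera adjusted p = 0.85).

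Of the fixed genes without inhibitors, PDR5 (0.59 ± 0.06), HSP12 (0.51 ± 0.09), ALD6 (0.45 ± 0.06), ADH7 (0.42 ± 0.15), FLO11 (0.38 ± 0.13), ARI1 (0.35 ± 0.07), ZWF1 (0.20 ± 0.08), YRO2 (0.20 ± 0.05), TPO1 (0.17 ± 0.06) and ADH6 (0.17 ± 0.05) were higher in the tolerant strain. GRE2 (-0.74 ± 0.05), PDR12 (-0.44 ± 0.08) and HSP26 (-0.21 ± 0.07) were lower, and HXT1 (0.08 ± 0.06) and GPD1 (-0.04 ± 0.05) did not pass. After quantile normalization ADH6, ADH7, ZWF1, TPO1 and FLO11 no longer passed. Camera also called the cell wall list higher (23 of 36 members higher, 5 lower, camera adjusted p = 0.033, and adjusted p = 0.76 with an estimated correlation) and the mitosis list (13 of 19 higher, 0 lower, camera adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation). Glycolysis genes were lower in 14 of 23 cases and higher in 2 (camera adjusted p = 0.002, and adjusted p = 0.49 with an estimated correlation). Hypoxic genes were lower in 13 of 23 and higher in 4 (camera adjusted p = 0.007, and adjusted p = 0.46 with an estimated correlation). The purine, Ehrlich pathway and thiamine lists were called lower too (medians -0.22, -0.26 and -0.27, or -0.33, -0.35 and -0.43 after quantile normalization, camera adjusted p = 0.0062, 0.034 and 0.033). In total camera called 10 lists higher and 7 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). The 3' to 5' ratio of WBP1 was 1.81 and 1.85 in the parental and 2.49 and 2.51 in the tolerant strain. Without replicate 1 of the tolerant strain without inhibitors, and also after quantile normalization, 3 lists were lower.

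A further comparison asks whether the tolerant strain without inhibitors already differs in the direction in which the parental strain moves. Across genes, which are not independent replicates, the difference between the strains without inhibitors and the parental response had a Pearson r of 0.385 and a Spearman rho of 0.346. They share the 2 parental arrays without inhibitors, and 100 simulations with no effect gave a mean r of 0.50. The observed covariance was 0.269 against a simulated 0.00575, a difference of 0.263. With these arrays split, 1 to each comparison, r was 0.368 and 0.370 and the covariance 0.257 and 0.265. Of the 308 features at least 2-fold higher in the tolerant strain, 228 also rose at least 2-fold in the parental response (49.1 from independent lists) and 6 fell. Of the 83 lower, 24 also fell (14.1) and 12 rose. The expected numbers leave out the shared arrays, so they are no values for a lack of effect, and these overlaps were not counted with the arrays split. GPH1, HXK1, MTH1 and GAC1, for example, had intensities of 2508, 3442, 1698 and 1738 in the tolerant strain without inhibitors, of 251, 407, 121 and 212 in the parental strain without and of 8466, 8630, 1766 and 1767 in the parental strain with inhibitors.

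With inhibitors, the tolerant strain had more transcripts of the translation machinery and of lysine synthesis, and fewer of the phosphate starvation response and of reserve carbohydrates. All 124 ribosomal protein genes were higher, by a median of 2.08 (1.92 after quantile normalization, camera adjusted p = 6.5e-33, and adjusted p = 0.39 with an estimated correlation). PDR5 (YOR153W) was 5.30-fold higher, at 9279 ± 114 against 1751 ± 63.7 (log2 2.41 ± 0.06, adjusted p = 5.4e-12). ADH6 (YMR318C) was 3.39-fold higher, at 11116 ± 105 against 3275 ± 60.4 (log2 1.76 ± 0.05, adjusted p = 1.3e-11). BIO5 was at least 126-fold lower. Of 5674 features, 2654 were higher and 1804 lower, 935 and 563 of them by at least 2-fold. Quantile normalization gave 2232 higher and 2195 lower and centring each array 2300 and 2097. The median over all features was 0.14 as deposited and 0.01 after quantile normalization.

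The largest rises over the parental strain were those of SFG1 (40.8-fold, 1 of 2 parental arrays above background), RPL41A (20.1-fold), RPL22B (16.5-fold), RPL9A (15.8-fold), UTP13 (14.6-fold, 1 of 2 parental arrays above background) and YAL037W (14.0-fold). RPA43 and SYO1 were at least 11.6-fold and at least 13.0-fold higher. The largest falls besides BIO5 were those of ZPS1 (126-fold), PHO84 (111-fold), VEL1 (107-fold), YOR387C, a close relative of VEL1 (60.1-fold), BIO3 (40.5-fold), BIO4 (38.5-fold) and YHR033W (35.3-fold). PHO84, for example, was at 67.1 ± 3.34 against 7538 ± 98.3.

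Of the ribosome biogenesis genes 89 of 90 were higher and 1 lower (median 2.08, camera adjusted p = 3.1e-18, and adjusted p = 0.43 with an estimated correlation), with ERB1 at 3.31 ± 0.07, BRX1 at 3.11 ± 0.08 and RRP5 at 2.88 ± 0.07. RPL22A, RPS24B and RPS8B were higher by 3.27, 3.10 and 2.94. Lysine genes were higher in 8 of 9 cases and lower in 1 (median 1.97, camera adjusted p = 0.0037, and adjusted p = 0.5 with an estimated correlation), with LYS4, homoaconitase, at 2.60 ± 0.07, LYS20, homocitrate synthase, at 2.29 ± 0.06, LYS12 at 2.14 ± 0.05 and LYS9 at 2.08 ± 0.06. Ergosterol genes were higher in 22 of 26 cases and lower in 2 (camera adjusted p = 0.0011, and adjusted p = 0.62 with an estimated correlation), with HMG1 at 2.14 ± 0.06, CYB5 at 1.97 ± 0.07, ERG8 at 1.21 ± 0.06 and ERG13 at 1.16 ± 0.05. The G1/S list was not called (camera adjusted p = 0.089), with 19 of 30 members higher and 7 lower. The cyclin genes CLN1, CLN2 and CLB6 were higher by 2.27, 2.04 and 2.73, and CDC6 by 2.06.

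Lower in the tolerant strain with inhibitors were 17 of 19 phosphate starvation genes (median -1.69, camera adjusted p = 3.4e-07, and adjusted p = 0.11 with an estimated correlation), and 2 were higher. PHO89 was at -4.97 ± 0.10, PHM7 at -3.17 ± 0.08 and VTC4 at -2.20 ± 0.06. Of the stationary phase genes 22 of 26 were lower and 3 higher (camera adjusted p = 8.0e-08, and adjusted p = 0.11 with an estimated correlation), with SNO1 at -5.02 ± 0.10, FMP45 at -4.32 ± 0.10, SNZ1 at -4.01 ± 0.08 and RTN2 at -2.54 ± 0.07. Of the trehalose and glycogen genes 18 of 19 were lower (camera adjusted p = 1.8e-07, and adjusted p = 0.39 with an estimated correlation), with GDB1 at -2.88 ± 0.07, GPH1 at -2.85 ± 0.08, GSY2 at -2.52 ± 0.08 and GSY1 at -2.11 ± 0.07. Gluconeogenesis genes were lower in 10 of 13 cases and higher in 1 (camera adjusted p = 0.0011, and adjusted p = 0.39 with an estimated correlation), with MLS1 at -3.14 ± 0.12, ADY2 at -2.23 ± 0.10, MDH2 at -1.76 ± 0.09 and JEN1 at -1.05 ± 0.08. Purine genes were lower in 12 of 18 cases and higher in 3 (camera adjusted p = 7.0e-04, and adjusted p = 0.39 with an estimated correlation). ADE17 (-3.73), GCV1 (-3.70) and GCV2 (-3.26) were lower, and IMD4, an IMP dehydrogenase, was higher by 2.70. Haploid and mating-type genes were lower in 16 of 28 cases and higher in 6 (camera adjusted p = 0.017, and adjusted p = 0.5 with an estimated correlation). MF(ALPHA)1, MFA2 and AGA2 were at least 11.2-fold, at least 12.4-fold and at least 9.87-fold lower, and STE12 was higher by 1.64.

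The aldehyde and multidrug lists were not called (camera adjusted p = 0.18 and 0.22). In the former GRE2 was higher by 1.22, and ALD3 (-2.67 ± 0.08) and ALD4 (-1.50 ± 0.07) were lower. In the latter ICT1 was higher by 2.55, and AQR1 (-2.94 ± 0.09) and PDR15 (-2.47 ± 0.09) were lower. Of the fixed genes, ARI1 (1.20 ± 0.07) and HXT1 (1.04 ± 0.06) were higher, and HSP12 (-2.28 ± 0.09), ALD6 (-1.29 ± 0.06), HSP26 (-0.74 ± 0.07), FLO11 (-0.54 ± 0.13), ZWF1 (-0.46 ± 0.08) and PDR12 (-0.30 ± 0.08) lower. ADH7 (-0.02 ± 0.15) did not pass. TPO1 (0.42 ± 0.06), YRO2 (0.25 ± 0.05) and GPD1 (0.17 ± 0.05) were higher as deposited, with values of -0.039, -0.19 and -0.25 after quantile normalization. Camera also called the respiratory chain list (32 of 35 higher, 2 lower, camera adjusted p = 1.5e-04, and adjusted p = 0.62 with an estimated correlation) and the mitosis list higher (median 0.83, camera adjusted p = 0.025, and adjusted p = 0.5 with an estimated correlation). It called the nitrogen catabolite repression (median -1.30, camera adjusted p = 4.8e-06, and adjusted p = 0.11 with an estimated correlation), beta-oxidation (median -0.67, camera adjusted p = 7.0e-04, and adjusted p = 0.15 with an estimated correlation), hexose transporter (median -1.35, camera adjusted p = 0.0046, and adjusted p = 0.43 with an estimated correlation) and heat shock lists (median -0.31, camera adjusted p = 2.1e-04, and adjusted p = 0.62 with an estimated correlation) lower. Quantile normalization changed the medians of the heat shock list to -0.77, of the respiratory chain list from 0.63 to 0.29 and of the ergosterol list from 0.65 to 0.25. In total 6 lists were called higher and 10 lower, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). The 3' to 5' ratio of WBP1 was 1.96 and 2.00 in the parental and 2.40 and 2.50 in the tolerant strain. Adjusted over the list alone, the member counts given here were the same.

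**Figure D3:**
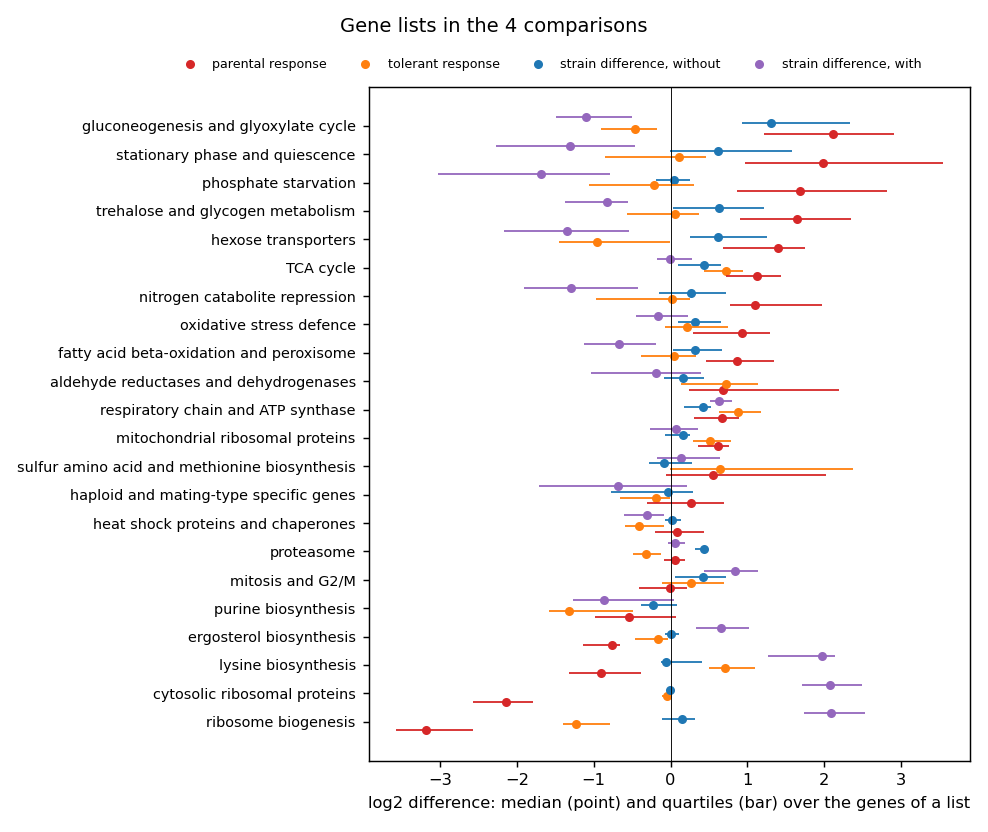
Median (point) and quartiles (bar) of the log2 difference over the measured genes of 22 gene lists in the parental response, the tolerant response and the strain difference without and with inhibitors. Of the 43 tested lists, only those that camera called at the preset correlation in at least 2 of these comparisons are shown. The ribosomal protein list lies at -2.14 in the parental response, -0.05 in the tolerant response, -0.01 between the strains without and 2.08 with inhibitors.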

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

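The tests of explanations for the ribosomal protein, baseline and zinc patterns, the bounds that decide them and the list of zinc genes were chosen only after the results they bear on were seen. The genes and lists given first differed between the strains in their response to the inhibitors, by the test of that difference, which was set beforehand.

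The response was higher in the tolerant strain for 2229 features and lower for 1915. The largest differences (log2, tolerant minus parental response) were 5.42 for SFG1, 5.00 for CGR1, 4.16 for RPL22B, 4.06 for UTP13, 4.04 for RPL41A, 4.01 for RPL9A, 3.94 for CLB6 and 3.88 for RRP36. On the other side they were -7.38 for BIO5, -6.67 for PHO89, -6.17 for GPH1, -5.96 for FMP45, -5.96 for SNO1, -5.94 for PHO84, -5.69 for YOR186W and -5.68 for DSF1. RRP36 and BIO5 with inhibitors and YOR186W and DSF1 without them were above background on 0 of 2 arrays of one strain, so these 4 sizes and their ranks rest on values at background. SFG1, CGR1 and UTP13 were not above background on both parental arrays with inhibitors, so their sizes and ranks rest on it in part. Fixed genes that differed were ADH6 (1.60), ARI1 (0.85), GRE2 (1.95), ALD6 (-1.74), ZWF1 (-0.67), PDR5 (1.82), TPO1 (0.25), HSP12 (-2.79), HSP26 (-0.52), GPD1 (0.21), HXT1 (0.97) and FLO11 (-0.91). TPO1 and GPD1 changed sign after quantile normalization.

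The list medians of this difference that passed at the preset correlation were 2.09 for cytosolic ribosomal proteins, 1.95 for ribosome biogenesis, 1.82 for lysine and 0.60 for ergosterol biosynthesis. Lower in the tolerant strain were gluconeogenesis (-2.89), hexose transporters (-2.39), stationary phase (-2.31), phosphate starvation (-1.90), trehalose and glycogen (-1.53), nitrogen catabolite repression (-1.29), beta-oxidation (-0.86), purine synthesis (-0.57), the TCA cycle (-0.37), the proteasome (-0.37), heat shock (-0.32) and oxidative stress (-0.30). After quantile normalization the medians were 0.30 for ergosterol, -0.68 for heat shock and -0.62 for the TCA cycle. With an estimated correlation the smallest adjusted p of these lists was 0.087.

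Ribosomal protein genes fell in the parental strain with inhibitors and hardly moved in the tolerant strain. A scaling of the arrays as the cause is argued against by the median of the list in the parental strain, which stayed at -2.00 after quantile normalization. Slower growth or a later stage of the parental cultures with inhibitors remains open and may account for it: stationary phase genes rose by a median of 1.98, and the DNA replication and G1/S list had a median of -0.69, short of the bound of -1 that was set with this value already known. No growth measurement was used here, so growth and the inhibitors themselves cannot be told apart for these genes. A direct effect of the inhibitors on the parental strain was not tested.

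Genes higher in the tolerant strain without inhibitors lay in the direction of the parental response. Noise of the shared parental arrays is argued against as the whole cause. The covariance stayed at 0.257 with the arrays split, against 0.269 with them shared. A state common to both parental cultures without inhibitors would remain in both parts of the split, so the split cannot address it. Less glucose left in the tolerant cultures at harvest would raise HXT2, HXT4 and HXT7, which low glucose induces. It would also lower HXT1, which needs high glucose. The former were higher by a median of 1.26, but HXT1 was not lower (0.075), so that part of the prediction was not met. With the parts divided, less glucose cannot be told apart from a difference of the strains. A heritable difference between the strains stays open and untested.

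Zinc genes, a list of 13 picked after their values were seen, had median log2 differences of -0.43 without and -1.64 with inhibitors (tolerant minus parental strain). A sequence difference under the probe sets of the tolerant strain would lower both of its groups alike where the signal lies well above background. The difference in response had a median of -1.17 over these genes, with 11 of the 13 lower and 2 higher. This value is the growth of the gap itself, in genes picked with it known, so it is no separate test. A loss alike in both groups would leave it near 0 and does not by itself account for the larger gap with inhibitors, except for members near background. VEL1, for example, was at 56.0 without and 45.0 with inhibitors in the tolerant strain. For the gap without inhibitors a sequence difference cannot be told apart, because 0 of the lower members were at background on both tolerant arrays and a partial loss of signal leaves the same trace. Less zinc shortage in the tolerant cultures is also open: 9 of the 13 genes were lower without inhibitors, including ZAP1, the zinc-responsive regulator (-0.43), ZRT1 and ZPS1, and 2 were higher, ZRT3 (0.24) and IZH1 (0.55). Zinc in the medium was not analysed here, and a heritable difference in zinc uptake was not tested.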

How the results depend on the processing

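The crossed pairing of replicates was chosen after seeing the data, and the other alternatives beforehand. Every count of genes stayed within 1.5 times its value under other pseudocounts, filters, variance models and probe set choices, and under the fit of 4 arrays, which was not run for the difference in response, and the cause of the shifts named here was not tested unless given. The fit of 4 arrays gave 2181 higher and 2228 lower in the parental response (2274 and 2314 in the main fit). In the tolerant response it gave 2001 and 2106 (1886 and 1971), so the strains differed less in these counts than in the main fit. Between the strains without inhibitors, 1496 features were lower after quantile normalization and 1554 after centring, which move the array-wide median, and 651 at an adjusted p under 0.01. Asking for at least 2-fold left, by construction, 904 higher and 964 lower in the parental response, 357 and 436 in the tolerant response, 308 and 83 between the strains without and 935 and 563 with inhibitors, and 947 and 781 for the difference in response. With an estimated correlation the lists called were 0 in both directions of all 5 comparisons, by a test whose power was not checked. Lists lower without inhibitors were 3 after quantile normalization and 3 without the filter, against 7. Without the filter 10 lists fell in the tolerant response (5 with it) and 7 had a higher difference in response (4 with it). The r of both responses was 0.335 without the filter and 0.385 with pseudocount 64, and that of the strain difference with the parental response 0.342 with pseudocount 64.

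Leaving out each array in turn, where the lone array of a group is assumed to vary like the others, gave 2165 to 2260 higher and 2175 to 2302 lower in the parental response, 1577 to 1946 and 1686 to 2040 in the tolerant response, 1649 to 2194 and 724 to 1057 between the strains without and 2401 to 2660 and 1564 to 1810 with inhibitors, and 2025 to 2267 and 1738 to 1889 for the difference in response. Lists called were 15 higher and 5 lower in the parental response throughout, 8 to 10 and 5 to 7 in the tolerant response, 9 to 10 and 3 to 7 between the strains without inhibitors (3 without replicate 1 of the tolerant strain without inhibitors), 6 and 10 with inhibitors and 4 and 12 for the difference in response. The r of both responses was 0.350 to 0.368, and that of the strain difference with the parental response 0.362 to 0.402.

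Of 418 results for named genes, 328 kept direction and call under all alternatives, 5 gained a call and 13 changed sign. The call was lost under at least 1 alternative by 79 (79 of 418 by asking for 2-fold, 11 at an adjusted p under 0.01). Apart from the fixed genes, the rule picked these genes from the same data for large changes or small p, which favours keeping the call. The 418 are therefore no measure of how stable an unpicked gene is. All 13 that changed sign were results of fixed genes. After quantile normalization the parental response was -0.054 for ARI1 and 0.31 for GPD1. The difference with inhibitors was 0.029 for ADH7, -0.039 for TPO1, -0.19 for YRO2 and -0.25 for GPD1, and the difference in response -0.11 for TPO1, -0.29 for YRO2 and -0.18 for GPD1. Over all features it turned 34 calls of the parental response, 56 of the difference with inhibitors and 23 of the difference in response. Centring gave -0.042 for HXT1 between the strains without inhibitors. Leaving out 1 array gave, in the parental response, -0.019 to 0.29 for ADH7, -0.029 to 0.15 for TPO1, -0.026 to 0.15 for PDR12 and -0.060 to 0.063 for ARI1, and -0.069 to 0.022 for ADH7 between the strains with inhibitors; the values on the other side of 0 did not pass.

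The replicate numbers did not pair the arrays: correlations of deviations between groups ranged from -0.24 to 0.09. The replicate block gave 2246 higher and 2286 lower in the parental response, 1846 and 1932 in the tolerant response, 2010 and 935 between the strains without and 2621 and 1775 with inhibitors, and 2182 and 1882 for the difference in response, with the same numbers of lists. With the numbers of the parental arrays without inhibitors exchanged, the crossed block gave 2288 higher and 2324 lower in the parental response and 2094 and 999 between the strains without inhibitors. Probe sets of another species, which this RNA should not bind, show a limit of the counts. Of 1746 such probe sets, the same test called 217 (12.4%) in the parental response and 12 in the tolerant response. It called 63 between the strains without and 76 with inhibitors, and 62 for the difference in response. Of these, in the same order, 15, 2, 9, 10 and 4 were at least 2-fold and above background. The background is itself a high percentile of these probe sets, so only a small part of the 1746 lay above it. The last counts are to be set against that small part. A change of at least 2-fold above background therefore does not exclude such calls.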

Other observations

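Biotin genes, a list of 5 written after their values were seen, formed a group of their own in the parental strain. BIO2, BIO3, BIO4, BIO5 and the biotin transporter gene VHT1 all rose with inhibitors there, by a median of 4.78, with BIO4 at 4.78 ± 0.10, VHT1 at 3.29 ± 0.07 and BIO2 at 1.57 ± 0.07. In the tolerant strain 0 of the 5 rose and 3 fell, with VHT1 at -0.05 ± 0.07 and BIO3 at 0.04 ± 0.09, changes that did not pass. VHT1 went from 623 ± 28.4 to 6117 ± 89.6 in the parental strain and from 747 ± 5.49 to 723 ± 21.5 in the tolerant strain. The difference in response had a median of -4.96. Because the list was picked for this pattern, no test of the list was run.

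Fatty acid oxidation and hexose transport moved apart in the strains. Of the beta-oxidation and peroxisome genes 19 of 23 rose in the parental strain and 0 fell (camera adjusted p = 1.9e-04, and adjusted p = 0.12 with an estimated correlation), with POX1 at least 12.5-fold, FAA2, an acyl-CoA synthetase, at least 8.41-fold, TES1 at 1.52 ± 0.09 and ECI1 at 1.49 ± 0.09. In the tolerant strain 8 rose and 7 fell (camera adjusted p = 0.97), and the median difference in response was -0.86 (camera adjusted p = 1.0e-03, and adjusted p = 0.16 with an estimated correlation). Hexose transporter genes rose in 10 of 13 cases and fell in 2 in the parental strain (camera adjusted p = 0.008, and adjusted p = 0.3 with an estimated correlation), with HXT4 at 1.44 ± 0.06, HXT7 at 1.39 ± 0.06, HXT9 at 2.09 ± 0.10 and HXT13 at least 4.89-fold. In the tolerant strain 3 rose and 9 fell (camera adjusted p = 0.051), with HXT2 at -1.51 ± 0.07, HXT9 at -1.74 ± 0.10, HXT7 at -1.21 ± 0.06 and HXT4 at -0.96 ± 0.06. The median difference in response of the hexose list was -2.39 (camera adjusted p = 0.0019, and adjusted p = 0.4 with an estimated correlation).

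In the Ehrlich pathway list, ARO9 and ARO10 changed in opposite directions in the strains. These genes, which encode an aromatic aminotransferase and a decarboxylase, rose by 2.42 and 1.97 in the parental strain, and in the tolerant strain they fell (-1.95 and -2.03), with differences in response of -4.37 ± 0.11 and -4.00 ± 0.11. The ester synthesis genes ATF2 and ATF1 fell (-2.44 and -1.18) in the parental strain, and SFA1, an alcohol dehydrogenase that also oxidises a formaldehyde adduct, rose by 1.07 and BAT2 fell by 1.05 in the tolerant strain. As a whole the list was not called in either response (camera adjusted p = 0.81 and 0.63). Its median difference in response was 0.37, opposite in sign to ARO9 and ARO10, and 0.09 after quantile normalization (camera adjusted p = 0.75). Arginine synthesis genes rose in 5 of 8 cases in the tolerant strain, which did not pass as a list (camera adjusted p = 0.066), with ARG1 at 2.39 ± 0.07, ARG3 at 2.14 ± 0.08, ARG8 at 1.16 ± 0.07 and CPA1 at 0.73 ± 0.07, while CAR2 of arginine breakdown fell by 4.08.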
